A study of Mus musculus with 2 samples.

How the data were processed

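Total RNA from 2 cultures of ICR mouse hippocampal cells was labelled with Cy3 and hybridized to Agilent 8x60K whole mouse genome arrays, per the labels. There was 1 array for the control culture and 1 for the TTX culture, both on the same slide. The cultures received 5 µM Ara-C against dividing glia and grew in 5.5% serum, per the labels. The treatment text is identical for both samples, and the groups were taken from the sample titles and source names. The dose is given as 2 µM in the design text and 2 mM in the source name, and the conflict could not be settled from the data.

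The authors' scanner files hold spot intensity on a linear scale, background-subtracted as processed signal, per the file headers. Feature Extraction is version 9.5.1.1 in the submitters' processing notes and 10.7.1.1 in the file headers. The deposited value table holds linear intensity as well. Its columns had the same quartiles on both arrays (median 24.9), as quantile normalization gives, and the series' design text names quantile normalization. Its probe differences correlated with those computed here at 0.9999 across 27398 measured probes. No deposited value was on a log2 scale, and all log2 values were computed here.

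Each array had 62976 spots, of which 59305 were not controls, for 55681 probes of 60 bases. Spots that Feature Extraction marked as non-uniform or population outliers (131 on control, 170 on TTX) were left out, and none was saturated. Processed signals were quantile normalized between the arrays, put on a log2 scale, and averaged over the spots of a probe. A probe was measured where at least 0.5 of its spots were well above background on both arrays, and a gene took the value of its brightest measured probe. Median local background was 58 on control and 60 on TTX.

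Genes were named from the probe annotation in the files, updated through a table of RefSeq symbols of assembly GRCm38.p6 that served for names only, while probe coordinates are those of mm9 in the file headers. Of the 55681 probes, 30845 had a symbol in that table, 27235 through their first accession, 83 through another and 3527 through the symbol, and 24836 had none. Counts of genes cover only symbols in the table, 22143 on the array and 14015 measured. This restriction was set when the analysis was coded, not in the plan.

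Without replicates there was no test between conditions. A size rule of 2-fold was used, and for 31 gene lists the median log2 difference was ranked among 10000 random lists of the same size matched on mean signal in 20 bins. A list was called when its percentile was below 2.5 or above 97.5. For genes above background on 1 array only, the bound was taken against the higher of the dim probe's own signal and the lowest signal of any probe well above background on that array (log2 values of 4.00 on control and 4.30 on TTX). The lists, size rule, alternatives and naming rule were fixed before the data were examined. The rule named the 10 highest and 10 lowest genes that passed 2-fold under 3 normalizations with probes of one sign and a curated symbol (417 genes did), the 5 largest bounds in each direction, up to 4 members of each list with the largest differences, and a set of genes always named. A few genes that the rule names are not reported here. Other list members and 5 further lists are named only where stated.

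Precision within an array was read from 261 measured probes with 10 spots each, less any spot marked as an outlier. The pooled SD of their spot-level difference was 0.15 log2, 0.26 in the lowest 20% of signals and 0.06 in the highest. The median Feature Extraction error of a difference was 0.20, and the median range between probes of 1 gene was 0.20. The 7 spike-in probes above background differed by a median of 0.06, from -0.11 to 0.27. Scaling on them moved the median of all genes from 0.01 to -0.09.

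Alternatives were 75th percentile scaling, spike-in scaling, no normalization between arrays, normexp background correction with an offset of 50, the authors' deposited values, no filter and a stricter filter on dim probes (above percentile 25), the mean over probes, 1.5-fold and 3-fold rules, a rule that also asked for 1.96 spot errors, at least 2 probes all past 2-fold, random lists matched in 5 bins, and list members above background on 1 array included at their bound.

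The steps were tested on simulated data made from the control array with spot noise as measured and 200 changed genes. For the TTX against control comparison, run on 14735 genes, log2 differences of 1.5, 2, -1.5 and -2 were recovered as means of 1.49, 1.99, -1.49 and -2.02 over 50 genes each, and no unchanged gene passed 2-fold. The simulation held no difference between cultures, RNA samples or labelling and no row gradient. It also took the background calls of the control array. Unchanged genes had an SD of 0.15 in it, against 0.52 for all measured genes in the data. It therefore checks the steps only and cannot give the rate of false calls among the genes counted here. Of 1000 random lists of 20 genes, 3.80% fell outside the central 95%, and all did so after a shift of 0.5. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp.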

Results

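RNA from mouse hippocampal cultures was measured on 2 single-colour microarrays, 1 from a control culture and 1 from a culture kept in tetrodotoxin (TTX), a blocker of voltage-gated sodium channels that stops action potentials. The cultures were made from embryonic day 16.5 hippocampus and harvested at 12 days in vitro, after 2 days of TTX in the treated culture. The labels disagree on the dose, which is 2 µM in the series' design text and 2 mM in the sample's source name. Each group had 1 array, so there were no replicates, no difference had a replicate check, and the number of arrays limits the precision. Signals were well above background at 54.2% of spots on the control array and 52.2% on the TTX array, and 14015 genes were measured on both. The comparison shows which transcripts differed between the TTX culture and the control culture, while firing itself was not measured.

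In the TTX culture many activity-regulated genes and neuropeptides, though not all, had much lower signals, and so did every measured gene of the list of cholesterol synthesis and SREBP target genes at its brightest probe. The list medians of endoplasmic reticulum and integrated stress response genes, potassium and HCN channels and presynaptic proteins were lower by smaller amounts. In these lists 22 of 23, 26 of 33 and 24 of 33 members were below 0. Single genes known from young neurons, Sox11, Stmn1 and Dcx, were higher, and the median of astrocyte markers was higher too. At the 2-fold size rule 473 genes were lower and 294 higher in TTX, while 83.7% of genes differed by less than 1.5-fold. The median log2 difference of all genes was 0.01, and the correlation of log2 signals across genes between the arrays was 0.982, where genes are not independent replicates.

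Among genes measured on both arrays, the largest difference was in Arc, a cytoskeletal protein of dendrites made in response to synaptic activity, whose signal was 4636 in control and 127 in TTX (log2 difference -5.19; probe on chromosome 15, 74499592 to 74499651, mm9). The nuclear receptor Nr4a1 was nearly as far apart (-5.09), followed among the immediate early transcription factors by Npas4 (-3.53), Egr4 (-3.05), Nr4a2 (-3.03), Fos (-2.61) and Egr1 (-2.50). Of the 19 measured genes of that list, 7 were at least 2-fold lower and none 2-fold higher. Their median was -0.59, below all 10000 random lists matched on signal, a percentile that describes these 2 arrays only. The list was not lower throughout, and 4 of its members were above 0.

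Effector genes induced by activity had a median of -1.23, also below every random list, with 14 of 23 at least 2-fold lower. The prohormone convertase Pcsk1 (-3.21), the AMPA receptor-binding pentraxin Nptx2 (-3.12), the G protein regulator Rgs4 (-2.95) and Bdnf (-2.37; signals of 3188 and 617) were among them. Inhba was lower by less than 2-fold (-0.67). Plk2, a kinase of synaptic scaling, was higher (0.67). Homer1 was close to level at its brightest probe (-0.16). Of its 5 measured probes the dimmest was at -0.89 and the others lay between -0.19 and -0.15, so they did not all give 1 value. Of the pentraxins, Nptx1 differed by -0.07, a value that changed sign with the scaling and came from a dim probe.

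Neuropeptides and granins formed another lower group, with a median of -0.98 and 9 of 19 members at least 2-fold lower. Adcyap1, which encodes the peptide PACAP, was at -4.83, and the secreted Vgf was at -4.35, from a signal of 37812 in control to 1856 in TTX. Grp (-3.43), Pnoc (-2.17), Npy (-1.59) and Cck (-1.22) were lower as well. The difference was not shared by all peptides: Sst differed by only -0.19 and the granin Scg2 by -0.40. The 10 lowest genes by the naming rule also held the receptor partner Ramp3 (-5.13, the same to 2 decimals at both of its probes), the parathyroid hormone-like peptide Pthlh (-4.60), Pdlim3 (-4.15), the G protein subunit Gng4 (-4.12, and -1.33 at its other probe) and Fam163a (-4.01).

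**Figure D1:**
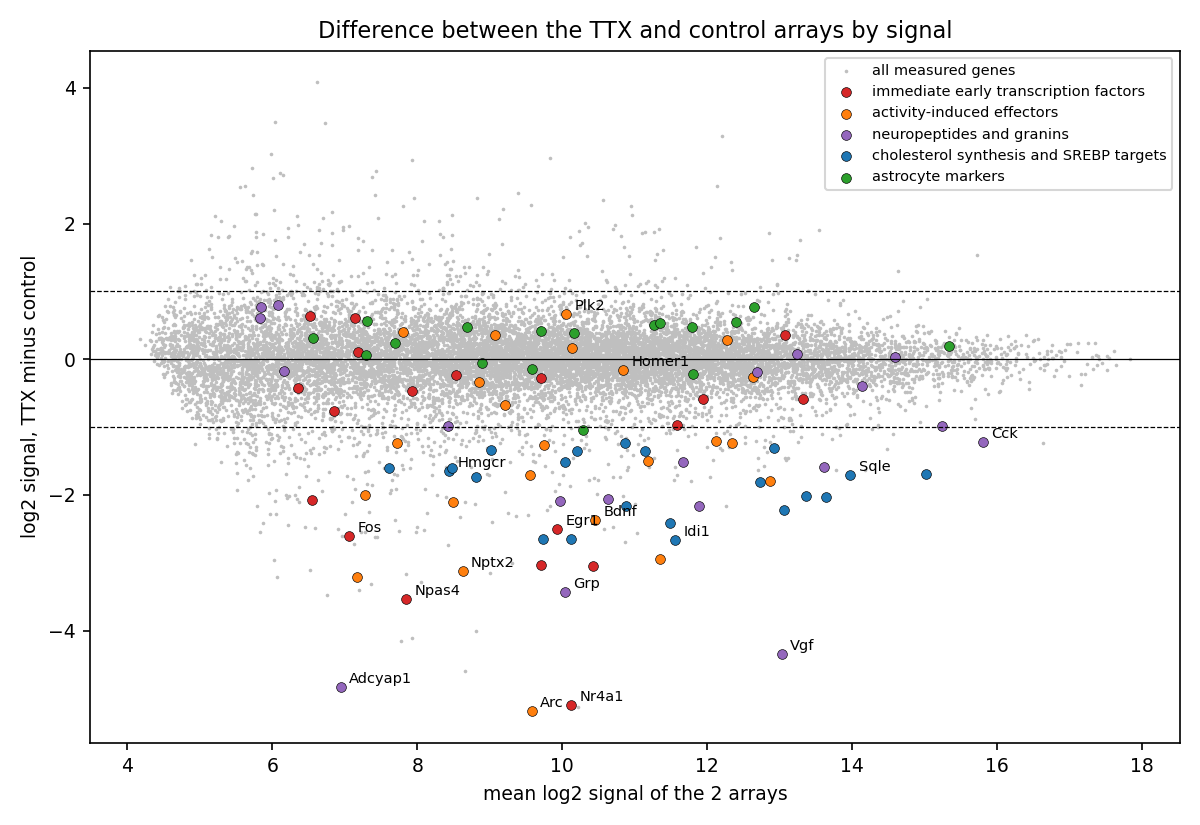
Log2 difference between the TTX and control arrays (vertical axis) against the mean log2 signal of the arrays (horizontal axis); each point is 1 of the 14015 measured genes, colours mark members of 5 gene lists and dashed lines mark 2-fold. Cholesterol synthesis genes all lie below the lower dashed line, and Arc lies at -5.19 and Nr4a1 at -5.09.

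Cholesterol synthesis was the most uniform of the lists in direction and in passing 2-fold. At the brightest probe all 21 measured genes were at least 2-fold lower in TTX, with differences from -2.66 to -1.23 and a median of -1.71, below every random list. An exception at another probe was Fdft1, with -1.31 at its brightest probe and 0.25 at its other one. Idi1, the isomerase that makes dimethylallyl diphosphate, was at -2.66, the sterol carrier Stard4 at -2.65 and the decarboxylase Mvd at -2.41. The signal of Idi1 was 7600 in control and 1203 in TTX. Stress-response genes were lower with similar uniformity at a smaller size: 22 of 23 were below 0, the median was -0.60, and 2 passed 2-fold. The pseudokinase Trib3 (-1.84) and the glutathione-degrading Chac1 (-1.46) were lowest, and Ddit3 (-0.97) and Sdf2l1 (-0.92) came next. Heat shock and oxidative stress genes had a median of 0.00, inside the central 95% of random lists, with Hspa1a at -0.99 and Hmox1 at 0.42.

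**Figure D2:**
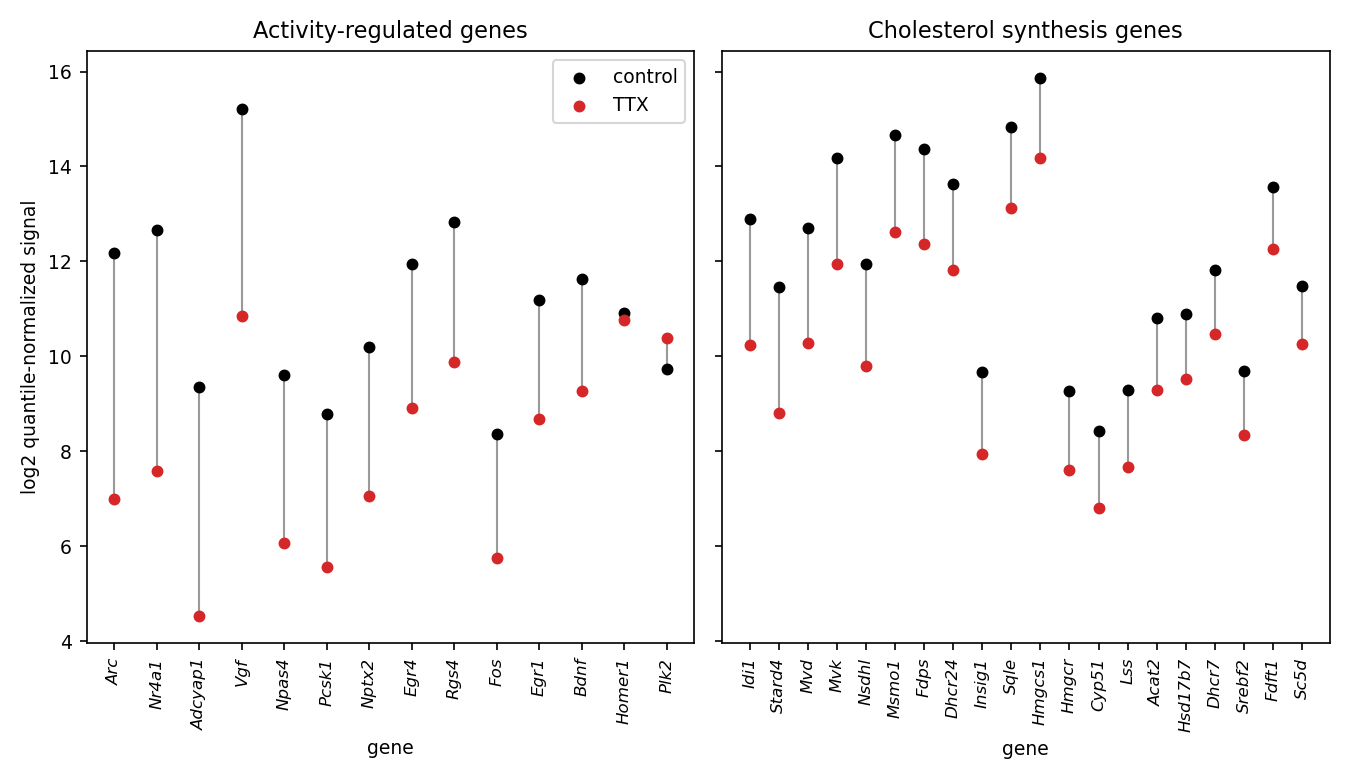
Log2 quantile-normalized signal (vertical axis) of activity-regulated genes on the left and of 20 cholesterol synthesis genes on the right, with the control array in black and the TTX array in red, joined by a line for each gene. The TTX point is the lower one for all genes shown except Plk2.

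Ion channels differed by family. Potassium and HCN channels had a median of -0.30, below every random list, with 4 of 33 at least 2-fold lower: Kcnv1 (-2.14), the M-current subunit Kcnq3 (-1.61), the calcium-activated Kcnn2 (-1.46) and the channel partner Kcnip3 (-1.14). Sodium channels had a median of -0.26, at percentile 2.37 of random lists, a call that ended with normexp background correction (percentile 4.23). Scn4b (-1.41, from a dim probe) was the only member at least 2-fold lower, and Scn11a (-0.79) came next. The adult subunit Scn2a was lower (-0.47) and Scn1a slightly so (-0.22), whereas the embryonic subunits Scn3a (0.75) and Scn3b (0.56) were higher. Scn8a was at 0.18 at its brightest probe and between -0.58 and 0.18 over its 3 probes. Calcium channels as a list stayed inside the central 95% with a median of 0.06. The T-type subunit Cacna1g was higher (1.06, with its other probe in the same direction), and so was Cacna1d (0.63).

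Glutamate receptors showed small and divided differences. AMPA receptor subunits Gria1 (0.09), Gria2 (0.07) and Gria4 (0.07) stayed within 0.1 of 0 and changed sign under at least 1 scaling, while Gria3 was higher (0.74). The median of their list, 0.07, also changed sign with the scaling. The auxiliary subunits were divided, with Cacng8 (-1.31) and Cacng5 (-1.05) lower and Cacng4 (0.95, from a dim probe) higher. NMDA, kainate and metabotropic receptors had a median of 0.23 at percentile 98.1, and that call ended with normexp background correction, with a stricter filter on dim probes and with no filter. Within the list the embryonic NMDA subunit Grin2b (0.44) and the kainate subunit Grik3 (1.22) were higher, and Grin1 (-0.47), Grin2a (-0.26) and Grin3a (-0.87) were lower.

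Inhibitory synapse genes had a median of -0.15 at percentile 4.16, inside the central 95%. The extrasynaptic subunit Gabrd (-1.42), Gabrg3 (-0.99), the scaffold gephyrin (Gphn, -0.83) and the GABA-synthesizing enzyme Gad1 (-0.70) were lower, while Gad2 was close to level (-0.11). Presynaptic proteins had a median of -0.19 at percentile 0.21. Sv2c (-1.10) and Unc13a (-0.63) were lower, Rims3 was higher (0.79), and the vesicular glutamate transporters differed in direction, with Slc17a7 at -0.22 and the developmentally earlier Slc17a6 at 0.74. Postsynaptic scaffolds stayed inside the central 95% with a median of -0.08. The calcium-dependent kinases Camk4 (-0.85), Camk2d (-0.73) and Camk2a (-0.54) were lower and Camk2b was higher (0.36), although the probes of Camk2a ranged from -0.56 to 0.29. Kalrn was at -1.23 at its brightest probe and at up to 1.16 over its 7 probes. Matrix genes were also inside (median 0.10), although Hapln1, which links hyaluronan in perineuronal nets, was at -1.99. Retinoic acid genes had a median of 0.06, and both of these medians fell below 0 with scaling on the spike-in controls. Among the retinoic acid genes, Rara (-2.47) and Cyp26b1 (-1.45) were lower and Dhrs3 (0.97) was higher. Oxidative phosphorylation genes were slightly lower, with a median of -0.17 at percentile 0.285 and no member past 2-fold, and Cycs at -0.56 was the lowest of them. Glycolysis genes (median -0.09) stayed inside.

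**Figure D3:**
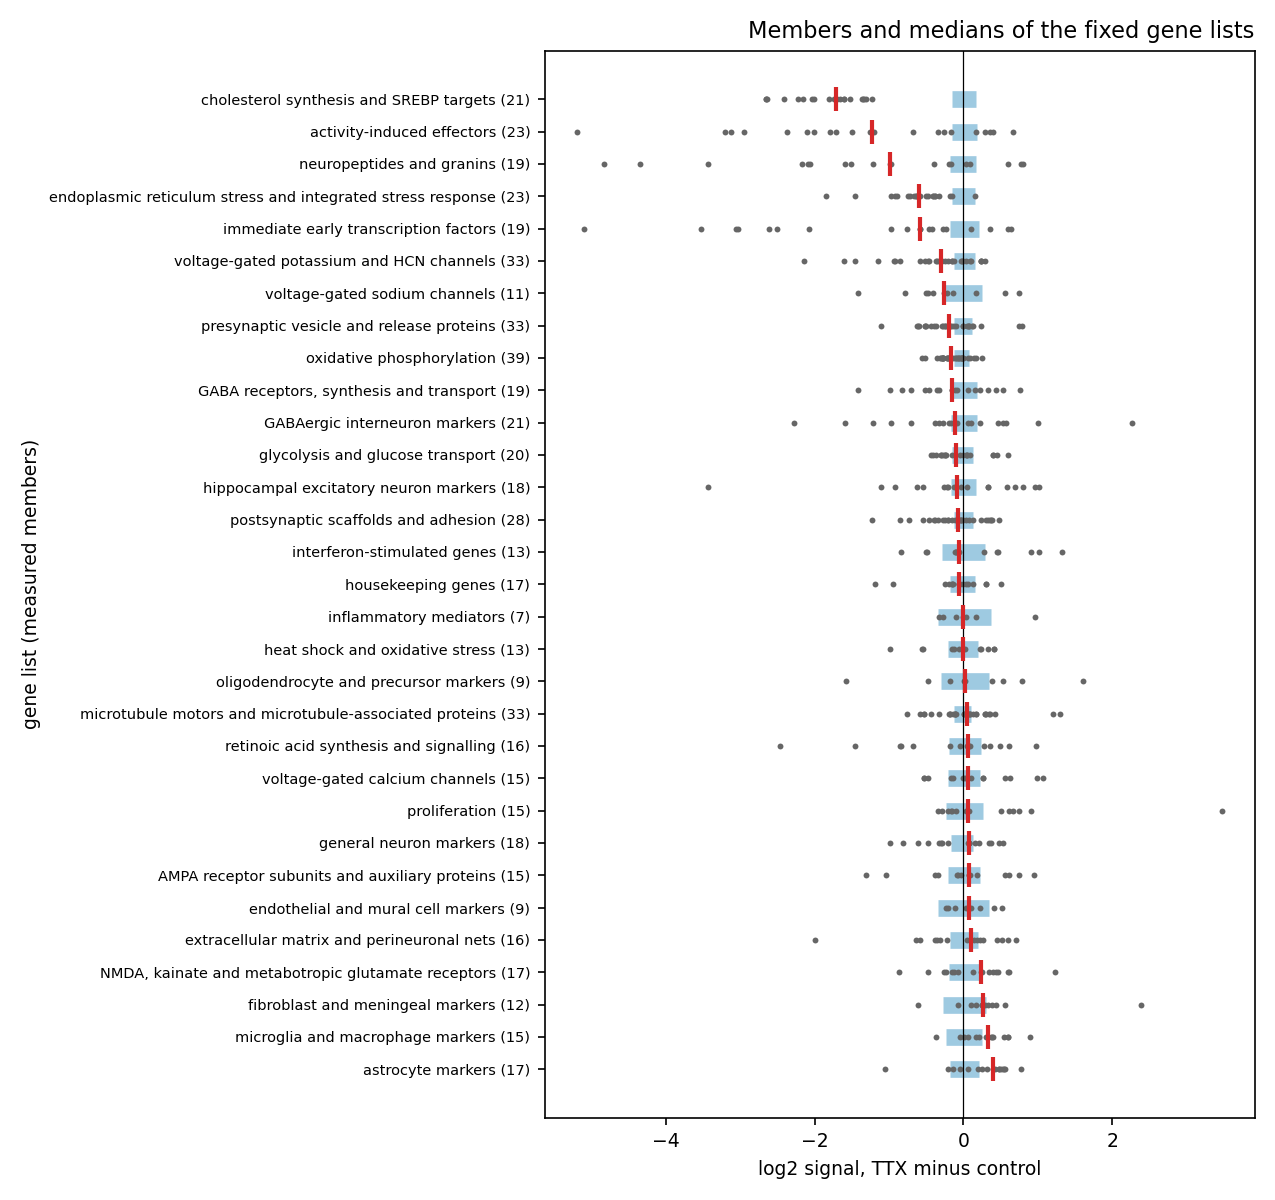
Log2 difference between TTX and control (horizontal axis) for each measured member (grey points) of the 31 fixed gene lists (vertical axis), with the list's median in red and the central 95% of medians of 10000 matched random lists in blue. Of the medians, 9 lie below the blue bar and 3 above it.

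Some single genes known from immature neurons were higher, though no fixed list covered them as a group. The transcription factor Sox11 was higher by 2.97, with 2.64 at its other probe, from a signal of 326 in control to 2549 in TTX. The microtubule proteins Stmn1 (1.30) and Dcx (signals of 1984 and 4564) were at least 2-fold higher, in a list of 33 whose median was 0.05 and changed sign with the scaling. Tubb3 was at 0.48. Excitatory neuron markers had a median of -0.08, inside the central 95%. Among them Tbr1 (0.97) and the dentate granule marker Prox1 (1.02) were higher, while Neurod6 (-1.10) and Grp were lower. General neuron markers had a median of 0.07, or -0.09 with scaling on the spike-in controls, and the genes of mature neurons Nefh (-0.98), Rbfox3 (-0.81) and Nefl (-0.61) were lower. In the interneuron list Calb2 was higher (2.27) and Lamp5 lower (-2.28), with a median of -0.12.

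Astrocyte markers had a median of 0.40 at percentile 99.99 of random lists, with Gfap (0.78), Sox9 (0.56) and Mlc1 (0.55) higher. The glutamate transporter Slc1a2 was an exception, at -1.05. Microglia markers had a median of 0.33 at percentile 99.4, a call that ended with the stricter filter on dim probes (percentile 90.1). Among them Tyrobp was at 0.59 and Laptm5 at 0.90, the latter from signals of only 17.3 and 32.1. Fibroblast (0.27), endothelial (0.07) and oligodendrocyte (0.02) marker medians lay inside the central 95%, the last of these falling to 0.00 with spike-in scaling. Fbln1 was the exception among fibroblast genes, higher by 2.38 with its 3 probes between 2.30 and 2.38. Inflammatory mediators (-0.01), interferon-stimulated genes (-0.06) and proliferation genes (0.07) had medians inside the central 95% that changed sign with the scaling. Housekeeping genes had a median of -0.06, with Actb at -0.15 and Gapdh at 0.00, but Hprt was at -0.95 and the transferrin receptor Tfrc had signals of 1856 and 811.

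Dim genes higher in TTX need the position of their spots beside them. Of the 10 highest genes by the naming rule, 8 were in the lowest 20% of control signals, and 7 of those had their spot in rows 1 to 192 of the 384 rows of the array: Tmtc2 (4.09), Atp6v0d2 (3.50), Mki67 (3.48), Zup1 (3.03), Zfhx4 (2.82), Ppp2r1b (2.78) and Tirap (2.74). The eighth, Akr1c18 (2.94), was at row 241. Among all dim spots, 6.84% in rows 1 to 48 were at least 4-fold higher on the TTX array, against 0.297% in rows 337 to 384. At 2-fold the shares of dim spots in these blocks were 14.0% and 4.58%. Counted as genes at 2-fold over wider blocks, 6.79% of dim genes were higher in rows 1 to 192 and 3.64% in rows 193 to 384. On that same measure genes brighter than this showed little slope, with 1.40% in rows 1 to 192 and 1.21% in rows 193 to 384. Mki67 was higher at both of its probes, in rows 59 and 120, but no other of the 15 measured proliferation genes passed 2-fold. Zfhx4 was at only 0.67 at its other probe, in row 290. Outside the dim genes, the highest, picked after their values were seen, were the choline transporter-like Slc44a5 (3.29 and 3.03 at its probes, from a signal of 1513 to 14791), Sox11, the LIM protein Csrp2 (2.56), the activin-binding follistatin Fst (2.45) and Prcd (2.38).

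**Figure D4:**
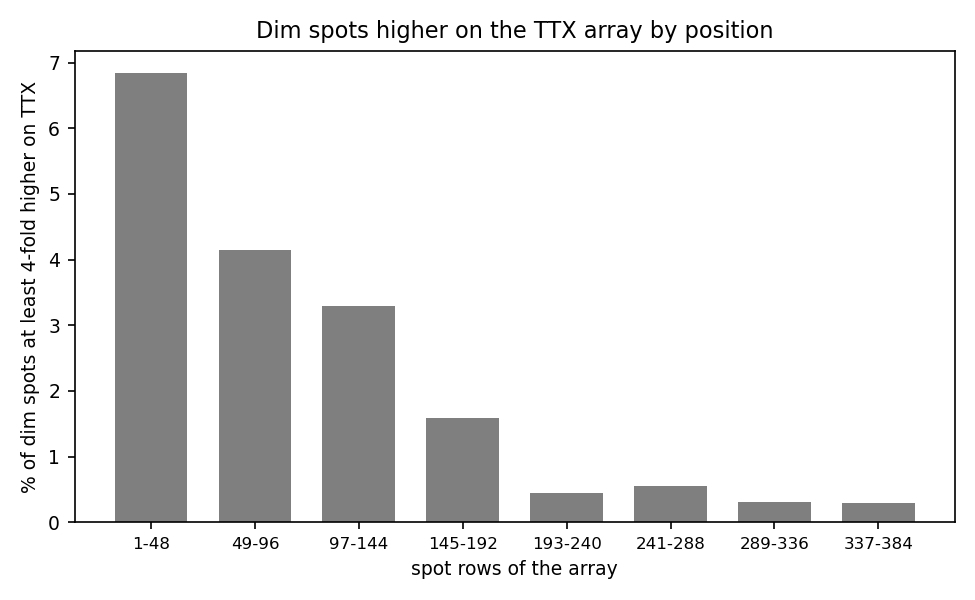
Percentage of dim spots (control signal in the lowest 20% of measured genes, or below it) that were at least 4-fold higher on the TTX array (vertical axis, bars from 0), by spot row of the array in blocks of 48 rows (horizontal axis). The percentage was 6.84 in the first block and 0.297 in the last.

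Some genes were above background on 1 array only, and for these only a bound can be given. On the control array alone there were 707, of which 123 had a bound of at least 2-fold. Rem2, a GTPase that limits calcium channels, was at least 24.0-fold lower in TTX (signals of 472 and 8.89), Oca2 at least 18.6-fold (366 and 16.0), Krt12 at least 17.1-fold (336 and 15.9), the prostaglandin synthase Ptgs2 at least 14.4-fold (282 and 6.60) and Opn3 at least 12.8-fold (264 and 20.7). On the TTX array alone there were 358, of which 194 had a bound of at least 2-fold. The largest were Kif11 (at least 21.5-fold; signals of 12.3 and 343), Olfr211 (at least 20.3-fold; 4.43 and 325), Fam25c (at least 18.4-fold; 13.1 and 294), Defa23 (at least 18.1-fold; 12.9 and 290) and Cfap221 (at least 17.3-fold; 16.0 and 277). All 5 lay in rows 16 to 51 of the array. Of the 311 probes above background on TTX alone with a difference of at least 2-fold, 275 were in rows 1 to 192 and 36 in rows 193 to 384, so this group follows spot position. The 366 such probes above background on control alone leaned the other way and less, with 150 in rows 1 to 192 and 216 in rows 193 to 384. Rem2 (row 281), Krt12 (row 263) and Opn3 (row 291) lay in the later rows, and Oca2 (row 145) and Ptgs2 (row 36) in the earlier ones.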

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

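Nothing in this part was tested beyond its values. Features that carry no symbol in the naming table lie outside the main counts, and 112 of the 5651 measured ones were at least 2-fold higher in TTX, which is what drew attention to them. Another 92 were at least 2-fold lower. Among the 14015 measured genes with a symbol, 294 were higher and 473 lower, so the share of higher features does not set this group apart. They are array names for clones, predicted transcripts and intergenic regions, and no biological explanation was tested. The lowest was at -3.35 and the highest at 3.62. The highest had a control log2 signal of only 4.22, in the dim range where spot position matters, and its position is not given here.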

How the results depend on the processing

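None of the tests in this part was chosen after the results were seen. No list or named gene past its threshold changed sign under any alternative run. Of the values that answer a comparison 17 moved, and 10 of these were counts of genes at least 2-fold higher and lower. These were 147 and 301 with normexp background correction, whose offset shrinks differences of dim genes by construction, 1063 and 1365 with no filter on dim probes, 1072 and 1208 with a 1.5-fold rule, 95 and 163 with a 3-fold rule, and 37 and 62 when all of 2 or more probes had to pass. The last compares with 69 and 108 such genes judged on the brightest probe alone. Scaling on spike-ins moved the medians of immediate early transcription factors to -0.76, activity-induced effectors to -1.40 and stress-response genes to -0.77. The neuropeptide median was -1.52 with the stricter filter, which drops dim members. The microglia median was 0.49 with 75th percentile scaling, 0.48 with no normalization and 0.18 with normexp, and the cause was not tested. Spike-in scaling gave 294 genes higher and 565 lower, of which 264 and 458 were the same genes as with quantile normalization. Among the other values, for named genes and the remaining lists, 168 moved and 1307 did not. For named genes alone, 63 of 165 moved with normexp and 58 of 165 with spike-in scaling. The cholesterol synthesis median stayed between -1.84 and -1.70 and the astrocyte median between 0.29 and 0.41 over all alternatives run. Calls that changed were those of NMDA, kainate and metabotropic receptors, sodium channels and microglia, given above, and 2 that appeared: glycolysis lower with normexp (-0.16, percentile 1.86) and fibroblast markers higher with normexp (0.21, percentile 98.9) and with no filter (0.29, percentile 97.7). Signal over background limits what can be said of dim genes, since spot noise was largest there. No paired analysis was possible because each group had 1 array, and leaving out an array or splitting the samples in other ways was not possible for the same reason.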

Other observations

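The tests of scaling and of astrocyte number for the cholesterol genes, of a row gradient for dim genes and of neuron number for glial markers were chosen only after the result was seen. The 5 further gene lists used here were also drawn up after the results of the fixed lists were seen, but before the values of their own members were looked at, and members already named or in a fixed list would have been left out. Genes named from them, and the Dusp genes, were picked after their values were seen. Directions of their medians were the same under each scaling, except for the LXR targets.

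The lower genes include several that act in negative feedback on the MAP kinase pathway. Of the 4 measured phosphatase genes in the fixed list of effectors, Dusp4 (-2.10), Dusp6 (-1.49) and Dusp1 (-1.23) were lower and Dusp14 was not (0.29). The further list of ERK feedback genes also holds transcription factors of the Etv family. In it 3 of 11 genes were at least 2-fold lower, Etv5 (-2.17) and Spry2 (-1.89) furthest, while Etv4 (0.38) and Spry1 (0.49) were above 0. Of the retinoic acid genes, the receptor Rara and the degrading enzyme Cyp26b1 were both lower. Tfrc and Hprt, often used as reference genes, were lower by close to 2-fold or more, so scaling on them would distort this comparison.

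Lower cholesterol synthesis was set against 4 explanations. The scalings tried did not account for it, since the least negative median under any setting was -1.70. They moved the median of all genes from 0.01 to no lower than -0.09, so they were too small to give another outcome. Fewer astrocytes are argued against, because astrocyte markers were higher (median 0.40). Lower activity of SREBP, the transcription factor of lipid synthesis, predicted that fatty acid synthesis genes would be lower as well, and as a list they were. Their median was -0.52, below all 10000 random lists, with 13 of 14 below 0. Only 1 passed 2-fold, Elovl6 at -1.09, and Acaca was at -0.85. Srebf1 (-0.04), Fads1 (-0.02) and Elovl5 (0.06) were close to level. A candidate explanation is therefore reduced SREBP activity in silenced cultures, with sterol genes moved further than fatty acid genes. Whether sterol excess lay behind it stays open, because the 6 LXR targets had a median of 0.021 and went both ways (Abca1 0.44, Mylip -1.05).

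Dim genes higher in TTX formed a group of 148 among the 2803 genes in the lowest 20% of control signals (5.28%). Choosing genes as dim on 1 array favours a higher value on the other, and the mirror choice gave more: 196 of the 2803 genes dimmest on TTX were at least 2-fold lower there (6.99%). The mirror set also holds genes that became dim because they fell far, such as Adcyap1 (-4.83) and Fos (-2.61). It therefore does not show what the choice alone gives. The number alone cannot tell whether there is an excess of higher genes. What sets the group apart here is its position on the array. Noise between the spots of 10-spot probes would give 5.72 such genes, or 31.7 at the upper end of the 95% interval. That estimate came from 490 spots of 53 dim probes, after spots marked as outliers had been left out. It may be too low for genes with 1 spot, so it does not decide whether noise gives the group. The spots of the 148 genes lay closer together than those of random sets of dim genes (percentile 0.50 of 1000 sets), as a local defect would give. The share was 6.79% in rows 1 to 192 and 3.64% in rows 193 to 384, a ratio of 1.86 with a 95% bootstrap interval of 1.34 to 2.65, so position may account for part of the group but whether it accounts for all of it stays open. Of the 24 such genes with another probe, 62.5% were higher by at least 0.5 at the median of their other probes (interval 40.6 to 81.2). Among all second probes, counted singly and of any brightness, the share was 14.4%. The interval includes shares below the majority that was set as the limit, so single-probe artifacts stay open.

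A lower share of neurons in the TTX culture is a possible explanation of the higher astrocyte and microglia markers, and it would raise the markers of all other cell types alike. These did not decide it. Markers of oligodendrocytes, endothelium and fibroblasts together lay 0.15 below the glial markers, with a 95% bootstrap interval over genes of -0.06 to 0.35. The fibroblast median was 0.27 (interval 0.14 to 0.41), inside the central 95% of random lists, and the intervals of oligodendrocyte markers (0.02, -0.48 to 0.78) and endothelial markers (0.07, -0.21 to 0.42) include both 0 and the glial medians. General neuron markers, which fewer neurons would lower, had a median of 0.07 (percentile 87.7), with 10 of 18 above 0. That median fell to -0.09 with spike-in scaling. The astrocyte and microglia markers lay 0.28 above the neuron markers (interval 0.11 to 0.70). This contrast does not show which of the 2 sides moved. With 1 culture per group, a difference between dishes and an effect of TTX on cell number or on glia were not separated.

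A shift towards transcripts of immature neurons predicted higher values for further genes of that stage. The 16 measured had a median of 0.34, above all random lists, with 12 above 0 and 4 below. Only 3 passed 2-fold, Cd24a (1.86), Sox4 (1.47) and Igfbpl1 (1.13), and St8sia4 was the lowest (-0.51). Some transcripts of immature neurons may therefore be held or regained under silencing, which a time course before and after TTX would test.

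Lower ERK signalling was set against the 11 measured genes of the ERK feedback list, which lie outside the fixed lists. Their median was -0.62 at percentile 0.01, with 9 below 0. Less ERK output in the TTX culture is a candidate explanation that a measurement of ERK activity would test. The list cannot separate it from the lower activity-regulated genes in general, and neither firing nor ERK activity was measured.

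Lower stress-response genes may point to less transcription by ATF4, the factor that drives amino acid synthesis and transport under stress. The 16 further ATF4 targets had a median of -0.48, below all random lists, with 13 below 0. Only 2 passed 2-fold, Eif4ebp1 and Cebpb (both -1.11), and Mthfd2 was at -0.93. The fixed list mixes endoplasmic reticulum stress genes with integrated stress response genes, and the further targets address only ATF4. Cth was higher (0.65), and the transporters Slc7a5 (0.01) and Slc3a2 (0.02) stayed close to 0. Both this and the sterol result rest on 2 arrays, and protein or metabolite levels were not measured.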
